A study of Mus musculus with 6 samples.

How the data were processed

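RNA was measured by sequencing in 6 samples of C3H10T1/2 cells, 3 treated with scrambled small interfering RNA and 3 with small interfering RNAs against Ring1a and Ring1b. Per the labels' protocols, RNA was isolated with Trizol and libraries were made by the Illumina TruSeq protocol. Per the submitters' processing notes, Bowtie 1.0.0, RSEM 1.2.12 and mouse build mm9 were used; the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

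The authors deposited a table of 20325 genes with a normalized signal per library. Its values are estimated read counts, which RSEM can split between near-identical genes, each column divided by a size factor (median normalization, as named by the deposited table). The authors also deposited a second table, of 323 differential genes, whose 6 columns are constant multiples (1 to 1.031) of the first. The fold that the authors deposited there is the ratio of the knockdown mean to the control mean with 0.01 added to each, which was recomputed for all 323 genes. The test behind that list is not given in the sources used here. Values of families with close paralogs or pseudogenes, such as ribosomal protein, histone and interferon-induced genes, are therefore uncertain.

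In each library the most frequent lowest value was taken as the value of 1 read: 0.259, 2.506 and 0.903 for control replicates 1, 2 and 3, and 0.565, 4.251 and 0.711 for knockdown replicates 1, 2 and 3. Dividing the deposited totals by these steps gave 51800000, 5400000, 15100000, 23200000, 4600000 and 18500000 reads. Of values up to 20 reads, 88.4 to 90.4% were whole multiples of the step within 0.1 read, so whole reads were not taken as recovered and no count test was run. A floor of 3 reads corresponds to 0.777 in control replicate 1 and 12.8 in knockdown replicate 2, so low genes are least certain in the latter. These floors cover counting error only.

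Genes with a mean of at least 10 over the 6 samples were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model, knockdown minus control, empirical Bayes with trend and robust options, two-sided), at a Benjamini-Hochberg adjusted p of 0.05. Groups of 3 against 3 give no exact permutation p below 0.1, so single genes rest on the model. Standard errors are those of the moderated model. Gene lists were tested with limma camera at a preset correlation of 0.01, two-sided, adjusted over 27 lists, and again with a correlation estimated per list and with fry. The estimated setting changed more than the correlation. Smooth muscle genes had an estimate of −0.015, below the preset, yet lost their call (camera adjusted p = 0.00143 at the preset and 0.155 with the estimate). A call lost with it is therefore no measure of correlation between genes alone. Cartilage genes also had an estimate below the preset (−0.010). In the other called lists it lay above, from 0.034 (stress response) to 0.936 (ribosomal), so there the preset may understate correlation. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover PRC1 and PRC2 subunits, Hox genes, other developmental transcription factors, the Wnt pathway, the BMP, TGF-beta, FGF and Hedgehog pathways, cyclin-dependent kinase inhibitors, p53 targets, cell cycle, adipocyte, cartilage, bone, matrix, smooth muscle, skeletal muscle, neuronal, epithelial, endothelial, leukocyte, germline, interferon, inflammatory, sterol, stress response, hypoxia and glycolysis, imprinted and ribosomal protein genes. All members of 19 lists were in the table; a single alias was used where the table gives an older symbol.

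Genes named are Ring1 and Rnf2; the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, a mean of at least 50 in the higher group, all 3 knockdowns beyond all 3 controls and a symbol that is not a predicted or clone name; and, per list, up to 4 members with the smallest adjusted p among those that passed, or the 2 most abundant where none passed. Genes outside this rule are marked as named after their values were seen. Values of 2 single genes are not reported here.

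Libraries were compared by Pearson correlation of log2 values and by a chi-square test per pair on estimated reads. No pair within a group agreed within sampling noise (lowest chi-square per degree of freedom 1.51), so no libraries were merged and each counted as a sample. The test covers counting noise alone, on estimated reads. It cannot tell separate cultures from separate preparations of the same culture. The labels give no batch or date. Transcript lengths were the median length of the protein-coding transcripts of each gene symbol in GENCODE M21, a newer build than the authors', used for lengths alone; 11950 tested genes (98.9%) had one.

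Simulated data were made from the control means with sampling noise and a fixed spread between like libraries, which was not estimated from these data. The code was tested on them for the knockdown against control comparison, with 12085 genes. It had to recover 200 changed genes, all with a control mean of at least 50. With 6 like libraries it recovered 99% of 2-fold and 100% of 4-fold changes with 8 false calls. With 1 divergent knockdown library (extra SD 1.23 log2 units) it recovered 0% of 2-fold and 41% of 4-fold changes with 0 false calls, and with that library left out 100% of both with 8 false calls. In the simulated lists the raised list was called (1 of 1) and 0 of 26 unchanged lists were. These lists came from 6 like libraries with genes varying independently. The run could not show false list calls from correlated genes or from a divergent library. Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, upper-quartile, total and quantile scaling, plain empirical Bayes, voom weights, the replicate number as a block, an adjusted p of 0.01, and each library left out. Library weights (limma's gene-by-gene estimate, taken because its default estimate did not converge), a correction of every library for transcript length, and, for the planned fit without knockdown replicate 2, the counts of list members and the list test with an estimated correlation were added after seeing the data.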

Results

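RNA from C3H10T1/2 cells, a mesenchymal progenitor line from C3H mouse embryos that can form cartilage, bone, fat and muscle, was sequenced at passage 10 to 15. The 6 samples fell into 2 groups of 3. The control group received a scrambled small interfering RNA, and the knockdown group received small interfering RNAs against Ring1a and Ring1b. These proteins are encoded by Ring1 and Rnf2 and are the ubiquitin ligases of Polycomb repressive complex 1 (PRC1), which marks histone H2A and keeps developmental genes silent. The comparison asked how the transcriptome of these progenitors changes when both ligases are depleted. The deposited values are estimated read counts per gene after median normalization, for 20325 genes. Deposited totals, rounded, were 13400000, 13600000 and 13700000 in control replicates 1, 2 and 3, and 13100000, 19500000 and 13200000 in knockdown replicates 1, 2 and 3. Because the lowest values of each library were mostly multiples of 1 step, depth before scaling could be estimated as 51800000, 5400000 and 15100000 reads for the controls and 23200000, 4600000 and 18500000 for the knockdowns. Every value below is in the deposited normalized unit, and log2 fold changes are knockdown minus control on the log2(value + 1) scale, which understates the change of low genes.

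Rnf2 was cut in every knockdown library, while the smaller difference in Ring1 missed the threshold with the main settings. Rnf2 stood at 815, 829 and 799 in the controls and at 129, 76.5 and 152 in knockdown replicates 1, 2 and 3, a 7.06-fold drop (log2 fold change −2.82, SE 0.28, limma adjusted p = 0.00946, lower in 3 of 3). It missed the threshold in 4 of the 6 fits that left out a library, those without control replicate 1, 2 or 3 (limma adjusted p = 0.0735, 0.0742 and 0.0852) and without knockdown replicate 1 (0.0646). With the replicate number as a block Rnf2 missed it too (limma adjusted p = 0.102). Ring1 stood at 336, 386 and 374 in the controls and at 162, 268 and 186 in the knockdowns, with a log2 fold change of −0.86 (SE 0.23). All 3 knockdown values of Ring1 lay below all 3 controls, but the difference missed the threshold (limma adjusted p = 0.104). Without knockdown replicate 2 it passed, at −1.06 (SE 0.10, limma adjusted p = 3.86e-06), as it did with all 6 under total scaling (0.0442) and, both added after seeing the data, a length correction (0.0498) and library weights (7.04e-07).

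Among the genes with the largest rises were several that the controls barely expressed. Vip, which encodes vasoactive intestinal peptide, went from 6.45 ± 1.51 to 395.6 ± 149.6 (SD, n = 3; 51.1-fold), and Chodl, encoding chondrolectin, from 1.03 ± 0.93 to 55.4 ± 11.5. Agtr2, an angiotensin receptor gene, stood at 0.52, 0 and 0 in the controls and at 98.4, 55.3 and 49.0 in the knockdowns. The homeobox gene Hoxc13 rose from 1.61 ± 1.01 to 65.2 ± 8.64 (SD, n = 3; log2 fold change 4.74, SE 0.39, limma adjusted p = 0.00758). The other genes of this group were Crmp1, Uchl1, the glutamate transporter gene Slc1a6, Igfbp2, Otor, Ptprd, Serinc2 and Dusp27, with log2 fold changes between 4.83 for Crmp1 and 3.94 for Dusp27. Uchl1 leaned on knockdown replicate 2, with values of 31.7, 170 and 32.0.

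The largest falls included matrix and secreted products. Acan, which encodes the cartilage proteoglycan aggrecan, fell from 194 ± 9.92 to 5.39 ± 2.73 (SD, n = 3; 32.3-fold lower), Fmod (fibromodulin) from 208 ± 21.7 to 13.04 ± 7.19, and Angptl1 (angiopoietin-like 1) from 2405 ± 200.1 to 132 ± 31.9. The peptidylarginine deiminase gene Padi2 dropped 27.5-fold, from 1385 ± 259 to 49.5 ± 10.1 (SD, n = 3; log2 fold change −4.78, SE 0.24, limma adjusted p = 0.00287). Cmtm5, Enpp6, C1qtnf3, Glt25d2 (a collagen galactosyltransferase), Serpina3n, the tyrosine kinase gene Bmx, Wfdc3 and Fam107a completed the group, with log2 fold changes between −5.35 for Cmtm5 and −3.94 for Fam107a. In all of these genes, rises and falls alike, the 3 knockdown libraries lay beyond the 3 controls, as the selection required.

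Over 12085 genes with a mean of at least 10, 387 rose and 215 fell (limma, Benjamini-Hochberg adjusted p under 0.05), 4.98% of those tested. Of these, 109 rose and 69 fell at least 4-fold. The groups did not overlap in 2483 genes that were higher and 2869 that were lower in the knockdown, where chance alone gives 10% of genes. Without knockdown replicate 2, 2855 of 11995 genes rose and 3136 fell, 49.9% of those tested. Counts of list members given below for that fit are to be read beside this share. Of the 602 calls made with all libraries, 598 were made again, all 598 in the same direction. Leaving out another library cost calls: without knockdown replicate 1 limma called 7 rises and 21 falls, without knockdown replicate 3 it called 37 and 57, and without control replicate 1, 2 or 3 it called 0 (1495, 1529 and 1475 genes at an unadjusted p under 0.05, against 2473 with all 6). Scaling every library to the same total moved the median log2 fold change of all genes from 0.01 to −0.14, so log2 fold changes are relative to the authors' median. With that scaling 184 genes rose and 116 fell, and with a correction for transcript length, added after seeing the data, 637 rose and 334 fell. With the replicate number as a block limma called 0 rises and 0 falls.

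Knockdown replicate 2 stood apart from the other 5 libraries. Its log2 values correlated with theirs, across genes, at 0.821 to 0.867, while all other pairs lay between 0.944 and 0.993. Cytoplasmic ribosomal protein genes took 19.7% of its total, against 4.9 to 5.7% in the other 5 libraries. Compared with the mean of knockdown replicates 1 and 3, short transcripts were higher in it and long transcripts lower. The median log2 difference was 0.81 in the bin of genes with the shortest transcripts (median 842 nt, 1 of 4 bins of about equal size) and −0.84 in the bin with the longest (median 4620.5 nt). Across genes, which are not independent replicates, the Spearman correlation of this difference with length was −0.487. It was −0.277 for the difference between knockdown replicates 1 and 3, and 0.128 for control replicate 2 against the other controls. The first principal component (70.1% of the variance) set this library furthest apart, at 115.5. On it knockdown replicates 1 and 3, at 0.49 and −6.45, lay on the same side of the controls (−39.4 to −34.5). The second component (23.4%) separated knockdown replicates 1 and 3 from the controls, with knockdown replicate 2 at 19.4 within the control range of 19.2 to 25.8.

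**Figure D1:**
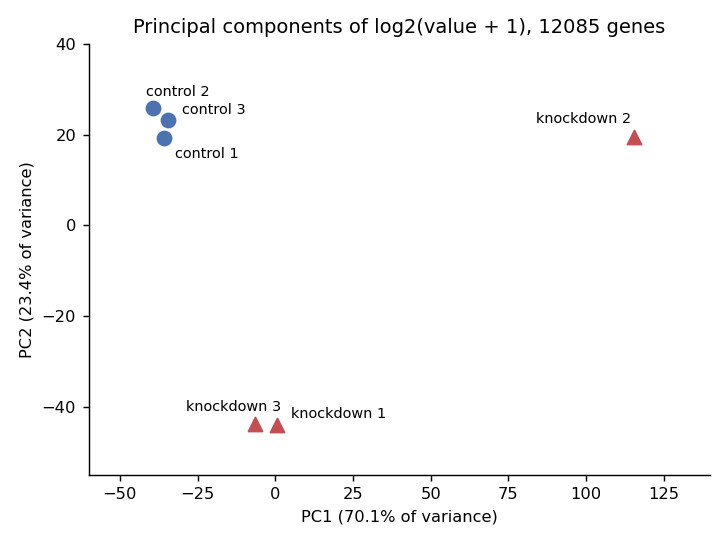
Principal components of the 6 libraries from log2(value + 1), with the first component (70.1% of the variance) on the x axis and the second (23.4%) on the y axis, in arbitrary score units. Circles are controls and triangles knockdowns. On the first component knockdown 2 lies at 115.5, knockdowns 1 and 3 at 0.49 and −6.45, and the controls at −39.4 to −34.5. On the second, knockdowns 1 and 3 lie at −44.1 and −43.7, the controls at 19.2 to 25.8 and knockdown 2 at 19.4.

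**Figure D2:**
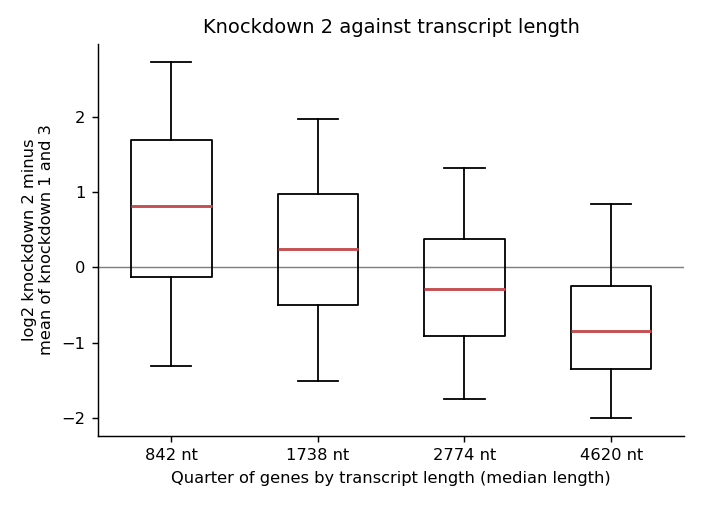
Log2 difference between knockdown 2 and the mean of knockdowns 1 and 3 (y axis), for 4 bins of genes by transcript length (x axis, median length in nt). Red lines are medians, boxes the 25th to 75th percentile and whiskers the 5th to 95th percentile; the medians go down from 0.81 through 0.25 and −0.29 to −0.84.

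Camera called cartilage genes lower as a list. Of 20 tested members of the cartilage differentiation list, 11 fell and 0 rose, 17 fell and 1 rose when p was adjusted over the list alone, and the median log2 fold change was −2.24. Lect1, which encodes the cartilage matrix protein chondromodulin, fell from 4172 ± 113 to 372 ± 24.1 (SD, n = 3; 11.2-fold lower), and the collagen gene Col9a1 from 3059 ± 316 to 631 ± 101 (4.86-fold lower). The cartilage transcription factor gene Sox6 dropped from 469.8 ± 23.4 to 64.4 ± 16.5 (SD, n = 3; log2 fold change −2.88, SE 0.23, limma adjusted p = 0.00758). The cartilage regulator Sox9 and its target Col2a1, named here after their values were seen, fell as well, Sox9 from 6711 ± 471 to 2199 ± 693 and Col2a1 from 27623 ± 1722 to 5040.1 ± 1879 (SD, n = 3). Camera called the list lower (adjusted p = 5.38e-13 over 27 lists), and it was the 1 list still called with a correlation estimated from the data (adjusted p = 0.0317 with an estimated correlation). Without knockdown replicate 2, 18 members fell and Pth1r, the parathyroid hormone receptor gene, rose (log2 fold change 1.85; chosen after its value was seen). With all libraries Pth1r did not pass (log2 fold change 2.51, limma adjusted p = 0.0793). With knockdown replicate 2 left out and the correlation estimated, the list's adjusted p was 0.234.

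**Figure D3:**
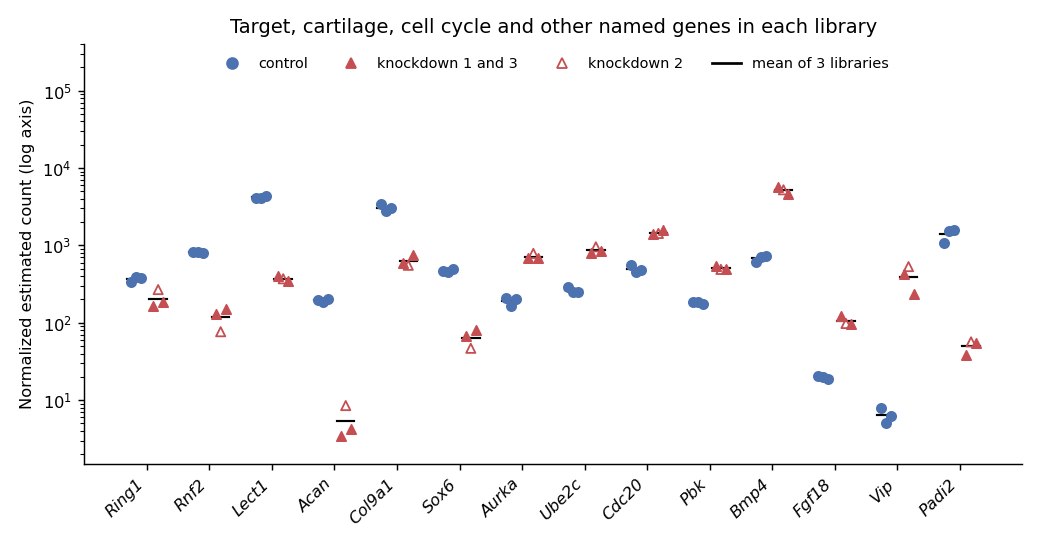
Deposited normalized estimated count (y axis, log scale) of 14 named genes (x axis) in each library; circles are controls, filled triangles knockdowns 1 and 3, open triangles knockdown 2, and bars the mean of 3. Rnf2, Lect1, Acan, Col9a1, Sox6 and Padi2 lie lower in every knockdown than in any control, as does Ring1, whose difference missed the threshold, and Aurka, Ube2c, Cdc20, Pbk, Bmp4, Fgf18 and Vip lie higher.

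Camera called genes of S phase and mitosis higher as a list at its preset correlation. Of 55 tested members, 31 rose and 0 fell, 46 rose when adjusted over the list alone, and in 48 members all 3 knockdowns exceeded all 3 controls. The mitotic kinase gene Aurka went from 190.3 ± 24.1 to 716 ± 61.1 (SD, n = 3; 3.76-fold), Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, from 261 ± 25.5 to 862 ± 84.8, and Cdc20 from 498 ± 48.5 to 1458 ± 92.0. Pbk rose 2.77-fold (log2 fold change 1.47, SE 0.14, limma adjusted p = 0.00894). The median log2 fold change of the list was 1.18, and camera called it higher (adjusted p = 1.31e-26; adjusted p = 0.101 with an estimated correlation). Without knockdown replicate 2 all 55 members rose, with a median of 1.33 (adjusted p = 0.276 with an estimated correlation).

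Of the cyclin-dependent kinase inhibitors, which slow the cell cycle, 2 of 7 tested members rose and 0 fell (3 adjusted over the list alone). These were Cdkn1a, encoding p21, from 2353 ± 50.8 to 4389 ± 814, and Cdkn3, from 45.7 ± 6.05 to 248 ± 139 (SD, n = 3). Cdkn3 encodes a phosphatase that is itself transcribed with mitotic genes. Camera called the list higher (adjusted p = 0.0321; adjusted p = 0.504 with an estimated correlation), but not without knockdown replicate 2 (adjusted p = 0.0761, 4 rose and 1 fell) or 3 (adjusted p = 0.0547). Cdkn2a, a well-known PRC1 target named after its values were seen, stood at 271, 226 and 237 in the controls and at 273, 999 and 234 in the knockdowns, high in replicate 2 alone, and did not pass (limma adjusted p = 0.481). Of 24 p53 target genes, 2 rose and 0 fell (8 and 1 adjusted over the list alone), namely Cdkn1a again and Gtse1, a G2 and S phase gene that restrains p53, from 159 ± 32.3 to 585 ± 220 (SD, n = 3). Camera called that list higher (adjusted p = 0.0488; adjusted p = 0.591 with an estimated correlation). It lost its call in 4 of the 6 fits that left out a library, namely control replicate 1 (adjusted p = 0.0643), control replicate 3 (0.0576), knockdown replicate 1 (0.116) and knockdown replicate 3 (0.232). It also lost it with fry (adjusted p = 0.112) and with upper-quartile scaling (0.0509), total scaling (0.0585) or the replicate number as a block (0.0633). Without knockdown replicate 2 camera called the list at the preset correlation, with 15 rises and 4 falls (adjusted p = 0.000442, or 0.276 with an estimated correlation).

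Signalling genes of the BMP, TGF-beta, FGF and Hedgehog pathways rose in part. Of 30 tested members, 6 rose and 0 fell (10 and 1 adjusted over the list alone), and the median log2 fold change was 0.47. Bmp4 went from 681 ± 56.3 to 5160.5 ± 494.6 (SD, n = 3; 7.56-fold; log2 fold change 2.92, SE 0.15, limma adjusted p = 0.00287), Fgf18 from 19.7 ± 0.67 to 105 ± 15.5, and the activin subunit gene Inhbb from 35.9 ± 4.45 to 194 ± 53.9. Etv4, a transcription factor gene induced by FGF signalling, rose 6.37-fold. Spry4 and Etv5, the other members that rose, had log2 fold changes of 2.76 and 1.32 and were named after their values were seen. Camera called the list higher (adjusted p = 0.00243; adjusted p = 0.664 with an estimated correlation), but not without knockdown replicate 3 (adjusted p = 0.0618) or with fry (adjusted p = 0.0541). In the fit without knockdown replicate 2, 20 of the 30 rose and 2 fell (adjusted p = 0.234 with an estimated correlation).

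Camera called the interferon-stimulated and inflammatory lists higher, with few single genes past the threshold. Of 40 interferon-stimulated genes, 4 rose and 0 fell (7 adjusted over the list alone), and in 28 members all 3 knockdowns exceeded all 3 controls. The 4 were Ifih1, a sensor of viral RNA, from 58.4 ± 8.55 to 148 ± 8.83, Parp14 from 122 ± 13.8 to 268 ± 37.2, Oas2 from 17.3 ± 2.75 to 62.1 ± 23.5, and Ifi44 from 28.3 ± 11.1 to 218 ± 147 (SD, n = 3). The list median was 0.999 and camera called it higher (adjusted p = 5.11e-07; adjusted p = 0.516 with an estimated correlation), but fry did not (adjusted p = 0.0541). Its members were a median of 1.09 log2 units higher in knockdown replicate 2 than in the other two knockdowns. Without that library 38 members were tested, the median was 0.67, 28 rose and 1 fell (camera adjusted p = 0.276 with an estimated correlation). Of 20 inflammatory genes, 3 rose and 1 fell (8 and 1 adjusted over the list alone). The growth factor gene Csf1 went from 1508 ± 69.7 to 3758 ± 733, and the chemokine genes Ccl7 and Cxcl1 from 7.29 ± 0.98 to 53.6 ± 30.9 and from 26.4 ± 2.20 to 55.7 ± 4.16, while the complement gene C3 fell from 562 ± 93.7 to 190.0 ± 35.2 (SD, n = 3). Camera called this list higher (adjusted p = 0.00527; adjusted p = 0.525 with an estimated correlation), though not without knockdown replicate 3 (adjusted p = 0.104) or among genes with a mean of at least 50 (adjusted p = 0.172), and fry did not call it (adjusted p = 0.0541). Leaving out knockdown replicate 2 gave 12 rises and 2 falls in it.

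Smooth muscle contractile genes had a median log2 fold change of 0.74. Of 13 tested, 1 rose and 0 fell (6 adjusted over the list alone), namely Tagln, encoding the actin-binding protein transgelin, from 151 ± 34.5 to 678 ± 283 (SD, n = 3). Camera called the list higher (adjusted p = 0.00143; adjusted p = 0.155 with an estimated correlation), and 10 rose and 0 fell without knockdown replicate 2. Of 29 genes of the unfolded protein and integrated stress responses, the folate enzyme gene Mthfd2 rose from 478 ± 77.5 to 929 ± 50.4 (SD, n = 3), 1 adjusted over the list alone, and 0 fell. That list was called higher (camera adjusted p = 0.0196; adjusted p = 0.485 with an estimated correlation) but not without knockdown replicate 3 (adjusted p = 0.109) or control replicate 1 (adjusted p = 0.0643). In the fit without knockdown replicate 2, 17 of the 29 rose and 3 fell.

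The 76 cytoplasmic ribosomal protein genes followed knockdown replicate 2. None passed in either direction (0 rose and 0 fell in limma, also adjusted over the list alone), and members were a median of 2.42 log2 units higher in that library than in the other knockdowns. Rpsa stood at 22161, 209250 and 21761 in the knockdowns and at 21246, 24191 and 25392 in the controls, and Rplp0 at 33438, 119460 and 32210 and at 30745, 34635 and 36105. Camera called the list higher with all libraries (adjusted p = 0.00261; adjusted p = 0.902 with an estimated correlation; fry adjusted p = 0.632) and lower without knockdown replicate 2 (adjusted p = 0.0227; adjusted p = 0.768 with an estimated correlation), where 25 members fell and the median was −0.13.

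Single genes of the Polycomb machinery and of its classical targets changed, and with the main settings camera called none of these 4 lists. Of 25 other PRC1 subunits and partners, E2f6, a repressor found in variant PRC1 complexes, rose from 248 ± 12.3 to 766 ± 131 and Scmh1 from 736 ± 24.2 to 1183 ± 63.7 (SD, n = 3), and 0 fell (the same counts adjusted over the list alone; camera adjusted p = 0.819), against 6 that rose and 6 that fell without knockdown replicate 2. Of 12 subunits of the methyltransferase complex PRC2, Phf19 rose from 29.99 ± 4.08 to 103 ± 23.1 and 0 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.943, median −0.10 and mean 0.04), against 5 and 4 without that library. In that fit 49.9% of all tested genes passed. Of 39 Hox genes, 10 had a mean of at least 10 and were tested. Among these Hoxc13 rose, while Hoxa2 fell from 622 ± 58.7 to 320.5 ± 24.2 and Hoxa3 from 596 ± 21.4 to 221 ± 59.2 (SD, n = 3; 2 and 3 adjusted over the list alone; 2 and 4 of 9 without that library). Camera did not call the Hox list (adjusted p = 0.911), whose median was 0.07 and mean 0.50 where the camera direction was lower. With no filter on low values, which lets in Hox genes near 0, the list was called higher (adjusted p = 0.000661).

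Of 179 other developmental transcription factors known as Polycomb targets, 59 had a mean of at least 10 and were tested. Foxl2 rose from 1.78 ± 1.56 to 20.2 ± 1.35, Tbx2 from 13.2 ± 1.63 to 49.7 ± 4.98 and Gata3 from 32.3 ± 3.61 to 90.0 ± 17.8 (SD, n = 3), while Sox6 fell (4 and 1 adjusted over the list alone). Camera did not call the list (adjusted p = 0.177), but called it higher with no filter (adjusted p = 0.0343) and without knockdown replicate 2 (adjusted p = 0.000155; adjusted p = 0.234 with an estimated correlation). In that fit 29 members rose and 5 fell. The 5 were Sox6 and, named after their values were seen, Hey2, Lhx9, Ebf1 and Foxd1, with log2 fold changes of −1.89, −0.91, −0.71 and −0.26.

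In the other lineage lists camera called no group with the main settings, although single genes changed. Of 20 adipocyte genes 4 fell (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.0544, or 0.0343 with no filter on low values; fry adjusted p = 0.0335): Pparg, the regulator of fat cell formation, from 661 ± 39.7 to 280.1 ± 56.5, Plin4 from 4210.1 ± 367 to 1679 ± 135, Dgat2 from 746 ± 65.7 to 188 ± 51.4 and Acaca from 4106 ± 165 to 2165 ± 398 (SD, n = 3). With all libraries none of 13 bone genes passed (0 in limma; 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.484), and the 2 most abundant, Col1a1 and Sparc, stood at 93702 ± 10971 and 39998 ± 406 in the controls and at 122040 ± 44063 and 74162 ± 14866 in the knockdowns (SD, n = 3). Of 40 collagen and other matrix genes, Fbln1 rose from 5.33 ± 1.02 to 83.9 ± 13.8 and Col8a1 fell from 806 ± 211 to 96.8 ± 54.4 (SD, n = 3; 1 and 1 adjusted over the list alone; camera adjusted p = 0.548). The fit that left out knockdown replicate 2 gave 4 rises and 8 falls among adipocyte genes, 9 and 3 among bone genes and 14 and 14 among matrix genes, and camera called none of these 3 lists in it (adjusted p = 0.345, 0.0980 and 0.717).

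Markers of other cell types were few. Of 11 neuronal genes, Tubb3 rose from 71.1 ± 7.32 to 180.5 ± 27.5 and Uchl1 rose, while the granin gene Scg2 fell from 132 ± 18.7 to 53.4 ± 6.32 (SD, n = 3; 4 and 1 adjusted over the list alone; camera adjusted p = 0.0688, 0.0459 with voom weights, fry adjusted p = 0.0217, higher). Of 7 endothelial genes, Eng, a TGF-beta co-receptor gene, rose from 643 ± 41.3 to 1189 ± 154 and the transcription factor gene Erg fell from 311 ± 13.3 to 42.0 ± 26.01 (2 and 1 adjusted over the list alone; camera adjusted p = 0.263, or 0.0397 with no filter, fry adjusted p = 0.0217, higher). With all libraries no skeletal muscle gene passed among 8 (camera adjusted p = 0.484), none among 4 leukocyte genes (0.367) and none among 5 epithelial genes (0.911), of which 0, 0 and 2 passed when adjusted over the list alone. Without knockdown replicate 2, 5 neuronal genes rose and 1 fell, 4 endothelial genes rose and 1 fell, 1 of 6 skeletal muscle genes rose and 2 fell, 1 of 4 epithelial genes rose and 2 fell, and 0 leukocyte genes passed. For the epithelial list the median was 0.21 and the mean 0.13 where the camera direction was lower. Skeletal muscle and leukocyte genes were a median of 2.34 and 0.99 log2 units higher in knockdown replicate 2 than in the other knockdowns. The filter on the mean of all 6 samples can admit genes high in that library alone, which raises such medians. Of skeletal muscle genes 8 were tested with it and 6 without, and of leukocyte genes 4 in either fit. The leukocyte genes Cd14 and Coro1a stood at 82.0, 162 and 63.2 and at 15.8, 85.0 and 13.8 in the knockdowns, Tnni1 at 41.3, 225 and 45.5 and Mef2c at 325, 255 and 415. In the controls their means were 89.6, 10.9, 132 and 473. The epithelial genes Pkp1 and Cdh1 had means of 38.0 and 20.2 in the controls and of 18.7 and 24.04 in the knockdowns.

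Camera called none of the remaining lists with the main settings. Of 19 genes of the Wnt pathway, the antagonist genes Nkd1 and Frzb went opposite ways, Nkd1 from 106 ± 9.68 to 300.3 ± 95.9 and Frzb from 1478 ± 57.8 to 224 ± 41.8, and Wnt5b fell from 582 ± 96.4 to 208 ± 75.1 (SD, n = 3; 4 and 3 adjusted over the list alone; camera adjusted p = 0.610, or 0.0343, higher, with no filter on low values). Of 27 hypoxia and glycolysis genes, Adm rose from 132 ± 29.0 to 461 ± 19.4 and P4ha2 from 1867 ± 68.5 to 3547 ± 357, and the glucose transporter gene Slc2a1 fell from 1946 ± 49.4 to 919 ± 49.4 (2 and 1 adjusted over the list alone; camera adjusted p = 0.647). Of 18 imprinted genes, the growth factor gene Igf2 rose from 32.9 ± 6.85 to 176 ± 60.8 (SD, n = 3; 1 adjusted over the list alone; camera adjusted p = 0.656). With all libraries none of 22 sterol synthesis genes passed (0 in limma, also over the list alone; camera adjusted p = 0.378), with Srebf2 at 7252 ± 403 in the controls and 5319 ± 2389 in the knockdowns (SD, n = 3). None of 9 germline genes passed either (0 in limma, also over the list alone; camera adjusted p = 0.911), with Zcwpw1 at 109 ± 9.24 and 165 ± 101 and Brdt at 42.8 ± 4.02 and 34.4 ± 4.18 (SD, n = 3). The germline median was 0.18, the mean −0.08 and the camera direction lower. With knockdown replicate 2 left out, 8 Wnt pathway genes rose and 3 fell, 3 hypoxia and glycolysis genes rose and 11 fell, 8 imprinted genes rose and 2 fell, 9 sterol synthesis genes rose and 2 fell, and 2 of 8 germline genes rose and 2 fell. Camera called none of these 5 lists in that fit (adjusted p = 0.162, 0.1004, 0.155, 0.0509 and 0.687), in which 49.9% of all tested genes passed.

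**Figure D4:**
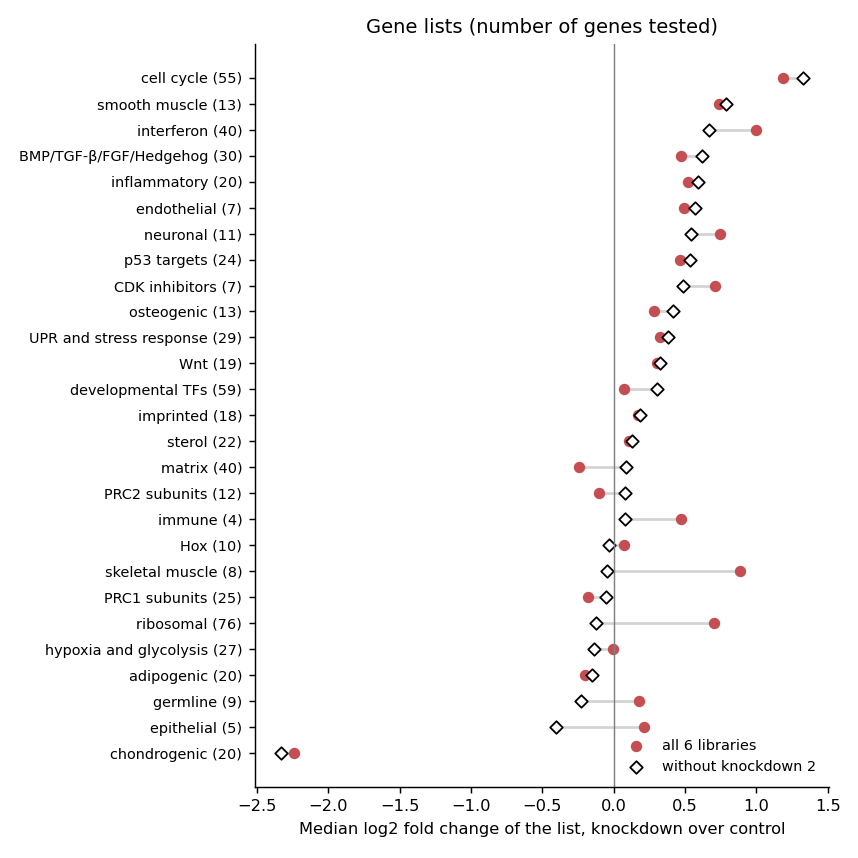
Median log2 fold change, knockdown over control (x axis), of each of 27 gene lists (y axis, number of tested genes in parentheses). Red circles use all 6 libraries and open diamonds leave out knockdown 2; the cartilage list lies at −2.24 and the cell cycle list at 1.18 with all libraries, and the ribosomal list moves from 0.70 to −0.13.

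In the authors' deposited table of differential genes, 323 genes differ by at least 4-fold, 231 higher and 92 lower in the knockdown. Rnf2 is in the authors' deposited table, 6.76-fold lower, and Ring1 is not. Of the listed genes, 248 had a mean of at least 10, and 173 of these passed limma in the listed direction. With knockdown replicate 2 left out, 239 of 241 passed, and 286 of the 323 (203 higher and 83 lower) stayed past 4-fold when the ratio was computed from the other 5 libraries. Without control replicate 1, 2 or 3, 0 of them passed limma. The authors chose the list on these samples, so these counts are not independent evidence of direction.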

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

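Library weights, the length correction and the combination of a left-out knockdown replicate 2 with an estimated correlation were chosen after seeing the data; the cause of a change was not tested unless given. The planned count test was not run, because whole reads were not recovered. Over 18 settings, 103 named genes gave 1830 values, of which 1276 kept their direction and side of the threshold, 514 no longer passed, 25 newly passed and 15 turned direction. Lists not called with the main settings gave 312 values of the same kind, 11 newly called and 31 turned; list values below are camera adjusted p. Depth limits low genes most in knockdown replicate 2, where 3 reads are worth 12.8. Leaving out each library in turn, which leaves fewer samples, gave 0 to 2855 rises and 0 to 3136 falls (0 to 159 and 0 to 90 at 4-fold), 0 to 239 genes of the authors' list, 5 to 11 called lists, Ring1 at −1.06 to −0.70 and Rnf2 at −3.02 to −2.53, where Rnf2 lost its call in 4 of the 6 fits (limma adjusted p without control replicates 1, 2 and 3, 0.0735, 0.0742 and 0.0852, and without knockdown replicate 1, 0.0646). In the same fits the called lists that changed ranged from 1.48e-05 to 0.0618 (BMP, TGF-beta, FGF and Hedgehog), 0.0218 to 0.0761 (kinase inhibitors), 0.000442 to 0.232 (p53 targets), 0.00064 to 0.104 (inflammatory), 0.00207 to 0.109 (stress response) and 1.5e-06 to 0.0227 (ribosomal, which turned without knockdown replicate 2). Uncalled lists that turned in some of these fits ranged from 0.555 to 0.890 (PRC1), 0.615 to 0.977 (PRC2), 0.672 to 0.968 (Hox), 0.162 to 0.990 (Wnt), 0.355 to 0.717 (matrix), 0.166 to 0.717 (skeletal muscle), 0.672 to 0.990 (epithelial) and 0.687 to 0.990 (germline), and log2 fold changes from −0.0652 to 0.50 (Cdh1), −0.30 to 0.37 (Cd14), −0.0399 to 0.74 (Zcwpw1), −0.10 to 1.53 (Rpsa) and −0.0404 to 0.91 (Rplp0). An adjusted p under 0.01 left 55 rises and 45 falls. Library weights (0.017 for knockdown replicate 2, 1.446 to 3.14 for the others) gave 3048 rises, 177 of them at 4-fold, and 3254 falls, 48.4% rises against 64.3%; Ring1 passed at −1.08, kinase inhibitors lost their call (0.0674), ribosomal genes turned (0.117), and matrix (0.842), Hox (0.955), PRC1 (0.619), PRC2 (0.619), skeletal muscle (0.653), Cd14 (−0.21), Cdh1 (−0.0596), Rplp0 (−0.0266) and Rpsa (−0.0866) turned. With an estimated correlation 1 list was called, cartilage, and the others gave 0.664 (BMP, TGF-beta, FGF and Hedgehog), 0.101 (cell cycle), 0.525 (inflammatory), 0.504 (kinase inhibitors), 0.516 (interferon), 0.591 (p53 targets), 0.902 (ribosomal), 0.155 (smooth muscle) and 0.485 (stress response). The smooth muscle estimate itself was −0.015, below the preset 0.01, so that call was not lost through the estimated correlation. The other lists that lost their call had estimates above the preset. These were 0.936 (ribosomal), 0.345 (BMP, TGF-beta, FGF and Hedgehog), 0.314 (interferon) and 0.184 (inflammatory). Cell cycle genes had 0.120, p53 targets 0.115, kinase inhibitors 0.112 and the stress response 0.034. For these lists the preset p may be too small, and how much of each loss comes from correlation cannot be told with this setting. With knockdown replicate 2 left out as well 0 lists were called by camera (10 with the preset correlation): 0.234 for cartilage, smooth muscle, inflammatory and BMP, TGF-beta, FGF and Hedgehog genes, 0.276 for cell cycle, interferon and p53 targets, 0.321 for kinase inhibitors and 0.411 for the stress response, while ribosomal, matrix and skeletal muscle (0.768 each), PRC1 (0.673) and PRC2 (0.681) turned. With fry, which tests each list on its own, 0.0541 was reached by BMP, TGF-beta, FGF and Hedgehog, inflammatory and interferon genes, 0.112 by p53 targets and 0.632 by ribosomal genes, none past the threshold, and Hox (0.632), PRC1 (0.957), PRC2 (0.887) and Wnt (0.957) turned; fry newly called adipocyte (0.0335, lower), neuronal (0.0217, higher) and endothelial genes (0.0217, higher), 3 of its 8 calls. Camera newly called developmental transcription factors without knockdown replicate 2 (0.000155), with library weights (0.00011) and with no filter (0.0343), Wnt (0.0343), adipocyte (0.0343, lower) and endothelial genes (0.0397) with no filter, and neuronal genes with voom (0.0459) and without control replicate 2 (0.044). The length correction gave 637 rises and 334 falls, Ring1 passed at −0.87, and Cd14 (−0.0400) and matrix (0.849) turned. A mean of at least 50, which tests fewer genes, left 52 rises at 4-fold and 108 genes of the authors' list, lost the inflammatory call (0.172) and turned PRC2 (0.937) and skeletal muscle (0.544). No filter gave 179 rises at 4-fold and turned epithelial (0.469) and Hox genes (0.000661). Equal totals gave 184 rises and 116 falls, Ring1 passed at −0.999, p53 targets lost their call (0.0585) and Cd14 turned (−0.0602); with upper-quartile scaling p53 targets gave 0.0509. Quantile normalization turned Cdh1 (−0.10), Col1a1 (−0.15) and PRC2 (0.861), and voom turned Cd14 (−0.0772). A check of deviations from each group's mean gave correlations of 0.17, −0.05 and −0.05 for replicates 1, 2 and 3. Control replicates 2 and 3 correlated best with knockdown replicates 3 and 2. Knockdown replicate 2 dominates the knockdown deviations, so this check cannot tell whether the replicate numbers pair the samples. With the replicate block limma called 0 rises and 0 falls, 0 of each at 4-fold and 0 genes of the authors' list (1866 genes at an unadjusted p under 0.05), Rnf2 kept −2.82 without passing, p53 targets gave 0.0633 and epithelial genes turned (0.994). Pseudocounts of 0.5 and 5 and plain empirical Bayes moved counts by less than 1.5 times (376, 388 and 440 rises, 211, 224 and 241 falls) and kept 10 called lists and the side of the threshold of both targets.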

Other observations

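Genes of the insulin-like growth factor (IGF) system and of tendon, named here after their values were seen apart from Igf2 and Igfbp2, changed in both directions. Igf1, the secreted growth factor gene, fell from 9248 ± 573 to 1385 ± 191 (SD, n = 3; log2 fold change −2.75, SE 0.17, limma adjusted p = 0.00404), while Igf2 was 5.06-fold higher. The binding protein genes Igfbp2 and Igfbp4 rose with log2 fold changes of 4.17 and 3.25, Igfbp4 from 283 ± 33.7 to 2840.3 ± 1186. Igf2bp3, which encodes an RNA-binding protein of fetal tissue, rose from 16.0 ± 1.64 to 185 ± 43.0 (SD, n = 3; log2 fold change 3.43). Tnmd, the tendon relative of chondromodulin, fell from 717 ± 81.3 to 141 ± 21.9, and Thbs4, a matrix gene of tendon, from 151 ± 31.9 to 12.6 ± 7.31 (SD, n = 3; log2 fold changes −2.35 and −3.66). These genes form no list fixed in advance, and no theme was tested for them.

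Some genes were silent in all controls (below 5) and above 10 in all knockdowns: 37 switched on this way and 14 switched off, or 59 and 23 without knockdown replicate 2. These limits rest on few reads, as 1 read was worth 4.251 in knockdown replicate 2 and 2.506 in control replicate 2. Hoxb9, chosen after its values were seen, stood at 0 in all controls and at 12.4, 12.8 and 14.9 in the knockdowns, at least 23.9-fold higher against a floor of 3 reads over the control group. Lbx1, a homeobox gene in no list fixed in advance and also chosen after its values were seen, stood at 0 in all controls and at 15.8, 25.5 and 10.7 in the knockdowns, at least 31.0-fold higher against the same floor. Both bounds take the knockdown mean as exact, and the Hoxb9 value of 12.8 in knockdown replicate 2 lies at the floor of 3 reads of that library. A hypothesis formed after these genes were seen was that Hox genes and other developmental transcription factors, the classical targets of PRC1, are over-represented among them. Of the 37, 3 were members of the 2 lists of such genes fixed in advance (Foxl2, Hoxb9 and Hoxc13), against 140 of 7409 genes silent in the controls (odds ratio 4.66). Without knockdown replicate 2 there were 5 of 59, Hoxb6 and Hoxc6 being added (odds ratio 4.95). The genes that prompted the hypothesis are those counted, so these ratios describe them and leave the hypothesis open.

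Of the tests that follow, the Rnf2 level in knockdown replicate 2 and the list medians without that library were chosen after the result was seen. The length correction was also added after seeing the data. The first pattern is that knockdown replicate 2 stood apart from the other 5 libraries. Low depth is argued against, because knockdown replicate 1 thinned to 4600000 reads still correlated with replicate 3 at 0.987. A control library under a knockdown label is argued against by Rnf2, which lay 3.39 log2 units below the control mean there (difference −3.39). A transcript length bias is a candidate explanation: the difference from the other knockdowns correlated with length at a Spearman rho of −0.487 across genes, against −0.277 between knockdown replicates 1 and 3 and 0.128 for control replicate 2, and length accounted for 23.3% of its variance (rho with GC content 0.309). The lengths are medians over all annotated protein-coding transcripts of a symbol and need not be those of the transcripts expressed. The share of 23.3% may therefore understate a length effect. The rest of that variance is open, and so are another batch or kit, degraded RNA and a biological difference of that sample, which were not tested.

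The second pattern is the higher level of the cell cycle list, of which 31 of 55 genes passed. It did not come from knockdown replicate 2 alone, since the median log2 fold change without it was 1.33. Nor did it come from transcript length as taken here, since the median after a length correction was 1.22, with camera still calling the list (adjusted p = 1.25e-24). The knockdown itself may raise these genes, as a hypothesis. Growth phase or confluence at harvest is open and was not tested. With an estimated correlation the list's adjusted p was 0.101, or 0.276 without knockdown replicate 2.

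The third pattern is the higher level of the interferon-stimulated list, of which 4 of 40 genes passed. Knockdown replicate 2 alone is argued against by the median without it, 0.67, and transcript length by the median after a length correction, 0.87, both with camera still calling the list at the preset correlation. With an estimated correlation its adjusted p was 0.516, or 0.276 without that library, and with fry 0.0541. The median without that library, over 38 tested genes, is below the 0.999 of all 6, over 40. Part of the rise may come from that library, though the change of genes tested can also move the median. A response to the small interfering RNA itself could raise such genes too; the controls also received one, but a difference between the RNA sequences cannot be separated from the knockdown in this design and was not tested.

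There are 10 splits of the 6 samples into 3 and 3. The real one gave 602 genes and the highest of the others 0, so 1 split reached the real count; 10 splits are too few for a share under 0.05.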
